A study of Mus musculus with 2 samples.

How the data were processed

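The count matrices of both libraries were taken as deposited, holding counts of UMIs per gene and cell barcode for 32285 features. Per the file headers and the submitters' notes they come from Cell Ranger 5.0.0 with the mouse genome build mm10, and the gene annotation used there is not given in the sources used here. Gene positions are from GENCODE vM21 on mm10. Reads were not analysed here. The median barcode held 5290.5 UMIs and 1613 genes in the sham library and 7324 UMIs and 2027 genes in the splenectomy library, and the lowest total was 501 UMIs in both. Cells with fewer than 200 genes (32 and 26 barcodes) and cells with more than 20% mitochondrial UMIs (58 and 72) were left out, and some barcodes failed both limits. Doublets were scored with Scrublet within scanpy at an expected rate of 0.05, and the highest scores were removed at 8 per 1000 cells for each 1000 cells, which took 302 cells (4.92%) and 200 cells (3.996%). Scrublet's own threshold called 131 cells (2.11%) and 3 cells (0.0590%) and was set aside for that reason.

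Counts of each cell were scaled to 10000 and logged, and both libraries were clustered together on 2000 variable genes, 30 principal components, 15 neighbours with shared-neighbour weights and Leiden resolution 1.0 with seed 7. Genes of 9 lists of cell states were left out of the variable genes. This clustering was chosen after 5 combinations of settings had been looked at with the cell numbers per library in view, and others of these combinations were run as alternatives. The 24 clusters were named by fixed markers of 19 classes, which gave 11 named classes. A name needed the highest mean score, at least 3 markers in 25% of the cells at 1.5-fold, and no larger number of markers of another class among the 10 leading genes. Clusters of low UMIs without a marker of their own among those genes stayed unnamed. Of the symbols on the lists, 9 list symbols (among them Mx1, Mx2, Ero1a and Xcl2) and 4 marker symbols (BC100530, Faim3, Trgc1 and Trgc2) were not among the features.

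For each class with at least 50 cells in both libraries, counts were summed over cells and divided by the class total to give CPM. Ratios are splenectomy over sham surgery, with exact intervals for the ratio of Poisson counts, and a count of 0 was replaced by 3. A gene was counted as higher or lower at 2-fold with at least 50 counts in the higher library. Named genes are the 10 highest and 10 lowest in neutrophil-like, monocyte-like and macrophage-like cells with at least 100 counts, 10% of cells and 1.5-fold, the 3 highest and 3 lowest in other classes with at least 50 counts, and genes set beforehand. Mitochondrial, ribosomal, haemoglobin, predicted and immune receptor variable genes were left out of the naming. The 21 gene lists were summed up by the median log2 ratio of members with at least 20 counts, and compared with 10000 random lists matched in 20 bins of expression. Intervals on list medians in the closing section are 95% bootstrap intervals over the members of a list, from 10000 draws, and do not cover counting error or differences between animals. A list with at least 5 members was taken to stand apart in the lowest or highest 2.5% of them. For shares of cells with a gene, cells were thinned to the largest of 500, 1000, 2000 and 4000 UMIs that kept 80% of the cells. Cells below that depth were left out, 226 and 111 of the neutrophil-like, 26 and 18 of the monocyte-like, 174 and 100 of the macrophage-like and, at 2000 UMIs, 11 and 11 of the B cell-like cells. The 80% rule was applied to the class shown and not to its background, and at 4000 UMIs 31 of 110 and 39 of 112 B cell-like cells were left as background.

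The steps were tested on simulated data with the totals of the libraries and 200 altered genes per class. Both simulated libraries were drawn as independent Poisson counts from 1 profile. The rates below therefore cover counting error only, and not differences between animals, between cells or in the mix of clusters. Genes altered 2.5-fold passed the 2-fold rule in 94.0%, 98.5% and 100% of cases in the neutrophil-like, monocyte-like and macrophage-like classes, and of unaltered genes 8 of 5972, 0 of 8463 and 0 of 9350 did. Intervals held the true ratio of CPM in 95.7%, 95.4% and 95.9% of genes. They held the planted fold in only 49.7% of genes in the neutrophil-like class, where altered genes moved the total and thereby all ratios by -0.19. Lists without a planted shift stood apart in 1, 2 and 4 of 100 cases, and 20 of 20 shifted lists did. A total of 17 alternatives were set before the data were examined and 6 were added later. Software was python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.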

Results

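Cells carrying CD45, a surface protein of leukocytes, were pulled from mouse hearts with magnetic beads and sequenced as single cells. The mice were C57BL/6 males aged 8 weeks that had been given either sham surgery or splenectomy. In both groups the left anterior descending coronary artery was occluded for 60 min and the heart was reperfused for 24 h. The spleen is a reservoir of monocytes and a site of immune responses, and the comparison asks how its removal bears on the immune cells of the injured heart. Each group holds 1 library, and the number of animals behind a library is not given in the sources used here. No test between the groups was therefore possible, and every difference below describes these libraries only. The sham library held 6210 cell barcodes with 53512625 unique molecular identifiers (UMIs), and the splenectomy library held 5087 barcodes with 48024013 UMIs. After filtering, 5838 and 4805 cells remained, with medians of 4972 and 7265 UMIs per cell. Intervals in this part are exact 95% intervals and cover counting error only. At least 1 UMI of Ptprc, the gene of CD45, was found in 79.6% of kept cells of the sham library and 79.4% of those of the splenectomy library. Xist, a transcript of female cells, was detected in 0 of 5838 and 0 of 4805 cells. Ddx3y, a Y-linked gene, was found in 34.4% and 42.0% of cells.

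Neutrophil-like cells made up 38.6% of the sham library (37.4 to 39.9) and 32.7% of the splenectomy library (31.4 to 34.1). Monocyte-like and macrophage-like cells together made up 41.2% (39.9 to 42.5) and 46.4% (45.0 to 47.8). Taken apart, monocyte-like cells held 16.8% and 23.9%, and macrophage-like cells held 24.3% and 22.5%. Natural killer cell-like cells were fewer in the splenectomy library, at 0.624% (0.422 to 0.890) against 1.18% (0.921 to 1.49), and plasmacytoid dendritic cell-like cells were more frequent there, at 0.832% (0.595 to 1.13) against 0.360% (0.223 to 0.549). B cell-like cells held 1.88% of the sham library and 2.33% of the splenectomy library, T cell-like cells held 1.18% and 1.54%, and the intervals of both classes overlapped between the libraries. Conventional dendritic cell-like cells held 5.24% and 4.52%, and nonclassical monocyte-like cells held 1.95% and 1.44%. Clusters without a class name held 6.56% and 7.41%. These shares depended on the clustering, which moved cells between the monocyte-like and macrophage-like classes and left others without a name. The difference lay between 1.24 and 10.8 percentage points in monocyte-like and between -15.57 and 3.11 in macrophage-like cells over 13 alternatives. In the same alternatives the neutrophil-like difference reached from -6.34 to 5.95 points and that of the combined class from -4.73 to 6.48, with 12 and 4 of the 13 values below 0. In the setting that gave 5.95, 1255 of 2254 neutrophil-like cells of the sham library and 465 of 1573 of the splenectomy library had lost their name, and in the setting that gave -15.57, 6 of 1421 and 467 of 1082 macrophage-like cells had.

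**Figure D1:**
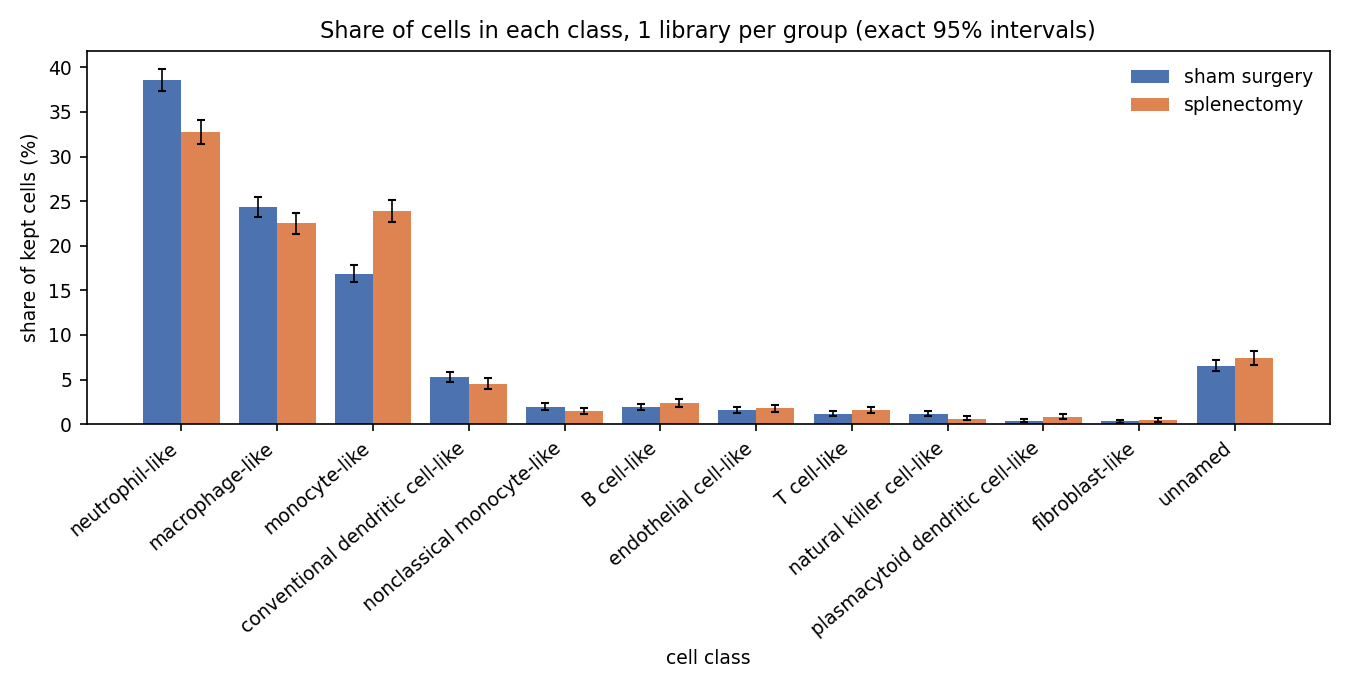
Share of kept cells (%) in each class for the sham surgery and the splenectomy library, with exact 95% intervals for counting error as bars. Neutrophil-like cells held 38.6% and 32.7%, and monocyte-like cells held 16.8% and 23.9%.

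Genes that answer to interferons, the cytokines of antiviral defence, were lower in the splenectomy library in each of the 3 large classes. In neutrophil-like cells 36 of 47 measured interferon-stimulated genes were at least 1.5-fold lower and 0 were as much higher, with a median log2 ratio of -0.86. In monocyte-like cells 43 of 49 were lower by that much and the median was -0.91, and in macrophage-like cells 43 of 50 were, with a median of -0.92. Ifit3, which encodes an antiviral protein that binds foreign RNA complexes (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731 in mm10), stood at 333 CPM (counts scaled to the total of the class) in sham neutrophil-like cells and 124 CPM after splenectomy. Its log2 ratio was -1.42 (-1.54 to -1.31) there and -1.50 (-1.68 to -1.31) in macrophage-like cells. Ifi27l2a, another interferon-induced gene, stood at 2875 and 1103 CPM in neutrophil-like cells. Rsad2, whose product viperin blocks viral replication, stood at 113 and 41.4 CPM in macrophage-like cells, and Ifi44 at 26.1 and 8.67 CPM in monocyte-like cells. Slfn1 in neutrophil-like cells, at 923 and 902 CPM, and Cxcl10 in monocyte-like cells, at 198 and 223 CPM, were the members with the highest ratios in those classes. The list's median was also low in conventional dendritic cell-like cells (-0.61, 24 of 47 members at least 1.5-fold lower and 1 higher), nonclassical monocyte-like cells (-0.76, 28 of 41 lower) and endothelial cell-like cells (-0.37, 15 of 40 lower). In B cell-like cells, where 13 members were measured, and in T cell-like cells the medians were 0.16 and -0.18, within the middle 95% of random lists. After each cell was thinned to 2000 UMIs, Ifit3 was found in 24.3% of sham neutrophil-like cells (22.4 to 26.2) and in 10.7% of those of the splenectomy library (9.20 to 12.4). Unthinned, the shares were 30.6% and 14.0%. B cell-like cells, taken as background, had it in 1.01% and 0%, and median depths were 3320 and 3765 UMIs in neutrophil-like cells and 3489 and 3691.5 in B cell-like cells. Within 12 single clusters of the 3 large classes the list's median lay between -1.50 and -0.45. With neutrophil-like cells grouped into 4 bins from fewest to most UMIs it was -1.07, -0.80, -0.39 and -1.13.

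Neutrophil-like cells of the splenectomy library held more transcript of granule and bone marrow stage genes, which neutrophils make while they mature. Of 24 measured genes of this list 13 were at least 1.5-fold higher and 1 was lower, with a median log2 ratio of 0.78. Cd177, a surface protein of part of the neutrophils (ENSMUSG00000052212, chromosome 7, 24743983 to 24760311 in mm10), was highest among the genes that met the limits for naming, at 37.8 CPM in the sham library and 201 CPM in the splenectomy library, a log2 ratio of 2.41 (2.23 to 2.60). Retnlg, a resistin-like protein of neutrophils (ENSMUSG00000022651, chromosome 16, 48872621 to 48874496), stood at 886 and 2647 CPM. Wfdc21 stood at 651 and 1543 CPM, Lcn2, an iron-sequestering granule protein, at 784 and 1851 CPM, and Ngp, a granule protein found in too few cells for the naming limits, at 12.9 and 75.3 CPM. Prtn3, a granule protease, went the other way at 14.2 and 9.23 CPM. Ffar2, a receptor for short-chain fatty acids, had a log2 ratio of 2.02 (1.76 to 2.29), and Wfdc17 of 1.60 (1.56 to 1.64). Saa3, an acute-phase protein, Enah, Fcgr2b, Schip1 and Fmnl2 completed the 10 highest, with ratios from 1.25 to 1.44. Plac8 (258.7 and 86.3 CPM), Ifi209, AW011738, Xaf1, Ly6i, Ifi207, Sh3bp1 and Otulinl joined Ifit3 and Ifi27l2a among the 10 lowest, with ratios from -1.58 to -1.11. S100a8 and S100a9, the alarmins that make up much of the neutrophil cytosol, had log2 ratios of 0.36 and 0.40, and Il1b and Cxcl2, a cytokine and a neutrophil chemoattractant, of -0.28 and -0.20. In cells thinned to 2000 UMIs, Cd177 was found in 6.11% and 24.6% of neutrophil-like cells (9.05% and 33.3% unthinned) and in 0% of B cell-like cells of either library, and Retnlg in 26.8% and 46.9%, with a background of 0% and 3.96%. S100a8, S100a9, Il1b and Cxcl2 were found in at least 99.2% of neutrophil-like cells of both libraries, where B cell-like cells had S100a8 in 26.3% and 29.7%, S100a9 in 37.4% and 41.6%, Il1b in 22.2% and 33.7% and Cxcl2 in 42.4% and 45.5%. In all, 49 genes were at least 2-fold higher and 77 at least 2-fold lower among 6053 with 50 counts. The class was led by different clusters. A cluster marked by Csf1, Il23a and Ifit3 held 48.7% of it in the sham library and 29.4% in the splenectomy library. A cluster marked by Retnlg, Wfdc21 and Stfa2l1 held 17.6% and 47.4%. Within the 3 largest neutrophil-like clusters the median of the granule list was 0.37, 0.41 and 0.51.

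**Figure D2:**
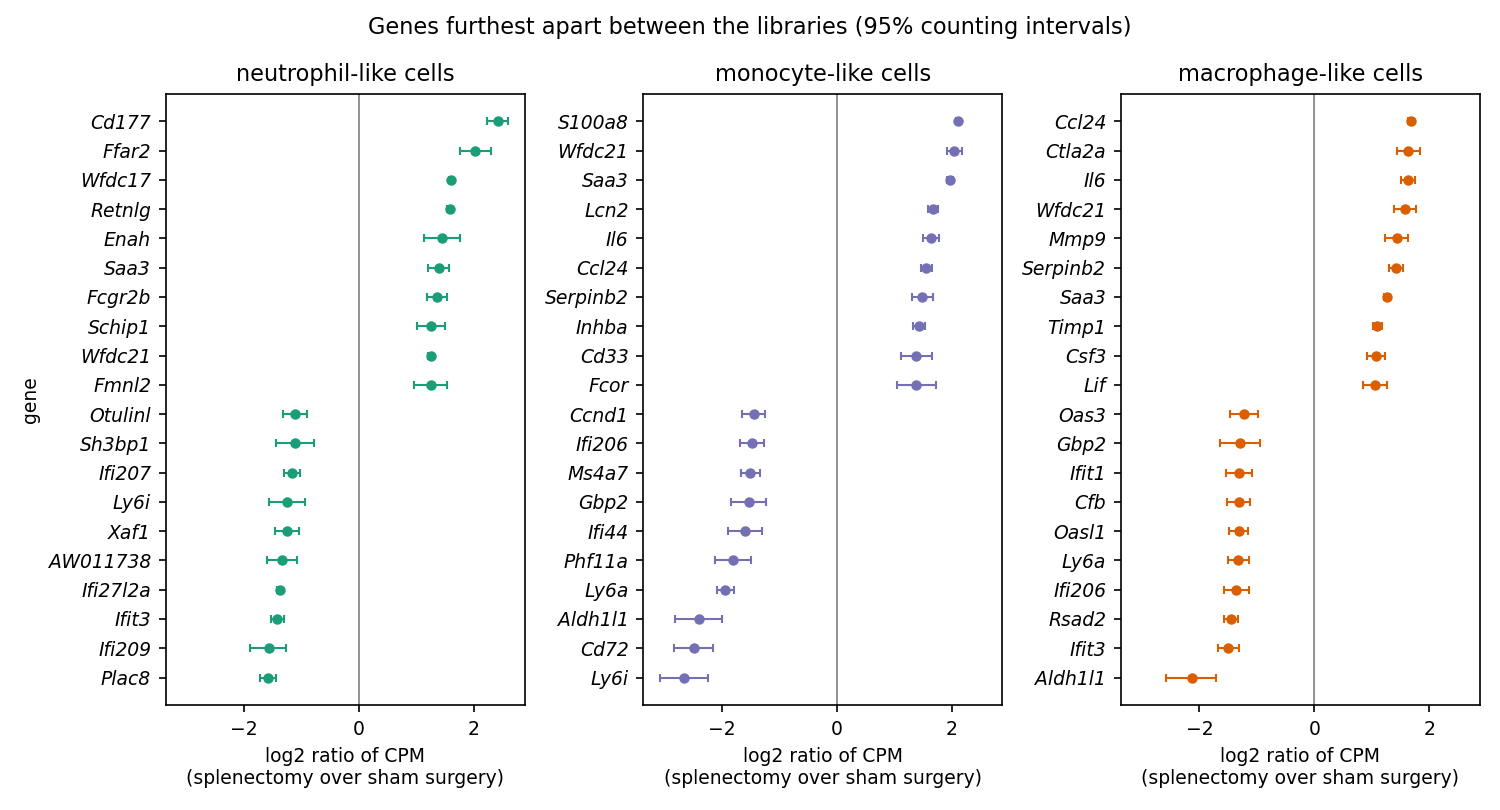
Log2 ratio of CPM, splenectomy over sham surgery, for the 10 highest and 10 lowest genes of each of the 3 large classes, with 95% counting intervals as bars. Cd177 stood highest in neutrophil-like cells at 2.41, and Ly6i lowest in monocyte-like cells at -2.65.

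Monocyte-like cells of the splenectomy library carried more transcript of secreted inflammatory proteins and less of Ly6c2, the surface antigen of classical monocytes. Of 35 inflammatory genes 10 were at least 1.5-fold higher and 1 was lower, with a median log2 ratio of 0.40. Il6, a cytokine of the acute-phase response (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981 in mm10), stood at 42.5 CPM in the sham library and 133 CPM in the splenectomy library, and Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) at 256 and 1000.4 CPM. Il1b stood at 5117 and 7817 CPM and Cxcl2 at 13077 and 19103 CPM, log2 ratios of 0.61 and 0.55. Ccl7, a chemokine for monocytes, was the lower member at 984 and 617 CPM. Ccl24, a chemokine for eosinophils, Serpinb2, an inhibitor of plasminogen activation, and Inhba, a subunit of activin, had log2 ratios of 1.56, 1.49 and 1.44, and Cd33 and Fcor of 1.39 and 1.38. S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035), Wfdc21 and Lcn2, all abundant in neutrophils, stood at 481 and 2075, 43.0 and 178, and 100.1 and 321 CPM. The median monocyte-like cell held 0 UMIs of Wfdc21 and of Lcn2 in both libraries, and 2 and 4 UMIs of S100a8. The ratios of Wfdc21 and Lcn2 thus rest on a part of the cells. At 4000 UMIs per cell S100a8 was found in 47.8% and 66.4% of monocyte-like cells, and in 48.4% and 30.8% of the 31 and 39 B cell-like cells that reached this depth, so that the share in the sham library was not above this small background. Monocyte-like cells had medians of 12653 and 12684.5 UMIs. Ly6c2 (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970) stood at 762 and 415 CPM, a log2 ratio of -0.88 (-0.92 to -0.83), and was found in 66.9% and 50.4% of thinned cells (80.3% and 69.4% unthinned, background 6.45% and 5.13%). Ccr2, the receptor that draws monocytes to tissue, stood at 511 and 509 CPM and was found in 78.1% and 78.9%. Ly6i, Cd72, Aldh1l1 and Ly6a were lowest among genes that met the naming limits, with log2 ratios of -2.65, -2.49, -2.40 and -1.94. Phf11a, Ifi44, Gbp2, Ms4a7, Ifi206 and Ccnd1 made up the rest of the 10 lowest, with ratios from -1.80 to -1.44. A total of 62 genes were at least 2-fold higher and 95 lower among 8508. A cluster marked by Ms4a4c, Aif1 and Apoc2 held 66.2% of the class in the sham library and 33.4% in the splenectomy library. One marked by Areg, Vcan, Il6 and Inhba held 16.8% and 41.6%. A cluster marked by Chil3 and Ly6c2 held 2.86% and 5.95% of all cells, a higher share while the class as a whole had less Ly6c2. Arg1 and Spp1, genes of wound-healing macrophages, had log2 ratios of 0.44 and 0.34, and the sign of each turned in 6 of 14 alternatives.

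Macrophage-like cells of the splenectomy library were higher in Ccl24, and, with both libraries clustered together, in several inflammatory genes and many single cell division genes. Ccl24 (ENSMUSG00000004814, chromosome 5, 135569937 to 135573049 in mm10) stood at 244 CPM in the sham library and 783 CPM in the splenectomy library, a log2 ratio of 1.68 (1.63 to 1.73), and was found in 22.1% and 38.6% of cells thinned to 4000 UMIs (32.9% and 50.4% unthinned) and in 0% of 31 and 39 B cell-like cells. Il6 stood at 41.7 and 129 CPM, Saa3 at 218 and 524 CPM and Timp1, an inhibitor of matrix proteases, at 97.6 and 209 CPM. Ctla2a, Mmp9, Wfdc21, Serpinb2, Csf3 and Lif were the other members of the 10 highest, with log2 ratios from 1.06 to 1.63. Of these, Mmp9 and Wfdc21 are neutrophil markers and were highest in neutrophil-like cells, at 2178 and 1097 CPM, and Ctla2a was highest in endothelial cell-like cells, at 1447 CPM. Of 36 inflammatory genes 5 were at least 1.5-fold higher and 0 lower, with a median of 0.30. Of 35 cell division genes 17 were higher and 0 lower by that much, with a median of 0.58. The list's UMIs were nearly the same part of the class total, at 32755 of 20597013 and 27038 of 16277758. Top2a, a topoisomerase of dividing cells, was found in 61 of 1421 and 52 of 1082 cells, and Mki67, another member, in 75 and 106. The 5 cells with most held 4.95% and 9.69% of the list's UMIs. The resident macrophage programme had a median of 0.29, with 6 of 26 members at least 1.5-fold higher, among them Cd163, a haemoglobin scavenger receptor, at 59.6 and 119 CPM. Lyve1, a hyaluronan receptor of resident macrophages (ENSMUSG00000030787, chromosome 7, 110850607 to 110863239), stood at 80.4 and 144 CPM and was found in 9.22% (7.67 to 11.0) and 15.1% (12.9 to 17.5) of thinned cells (12.3% and 18.8% unthinned), with a background of 0%. Timd4, a receptor for dying cells, was found in 4.25% and 5.60%, and those intervals overlapped. MHC class II genes, which present antigen to T cells, had a median of -0.31, with H2-Ab1 at 332 and 205 CPM, but the median was 0.00278 with at least 500 genes per cell and 0.65 within the cluster marked by Ccl24, Serpinb2 and Il6. Aldh1l1, an enzyme of folate metabolism, was the lowest named gene at 14.0 and 3.19 CPM, a log2 ratio of -2.13 (-2.59 to -1.70). Ifi206, Ly6a, Oasl1, Cfb, Ifit1, Gbp2 and Oas3 joined Ifit3 and Rsad2 among the 10 lowest, with ratios from -1.36 to -1.22. Arg1 stood at 1936 and 2503 CPM, Spp1 at 9932 and 9909, Il1b at 2421 and 3618, and Cxcl2 at 15676 and 19396. Thinned, Arg1 was found in 67.4% and 67.2% of cells and Spp1 in 76.9% and 73.0%, where B cell-like cells had Spp1 in 32.3% and 28.2%. In all, 64 genes were at least 2-fold higher and 54 lower among 9387, and the same cluster, marked by Spp1, Fabp5 and Arg1, held 58.4% and 46.5% of the class. A cluster marked by Ccl24, Serpinb2 and Il6 held 5.63% and 15.9% of it, and the log2 ratio of Ccl24 in the class lay between 0.35 and 1.68 over 14 alternatives. Within the cluster marked by Spp1 cell division genes had a median of -0.29 and the resident programme of -0.14, and the division genes were higher in a cluster marked by Gdf15, Pmp22 and Mmp12, at 0.80. A cluster marked by Lyve1, Cbr2 and Folr2 held 3.51% (3.05 to 4.02) and 3.70% (3.19 to 4.28) of all cells. The resident programme had medians of 0.08 within it, 0.07 in the cluster marked by Gdf15 and -0.36 in that marked by Ccl24. It reached 0.81 only in a cluster marked by C1qb and Pf4 with a median of 1260 UMIs per cell. With the libraries clustered apart, the medians of cell division and inflammatory genes were -0.00400 and -0.0188, genes at least 2-fold higher and lower numbered 16 and 128, and Il6, Serpinb2 and Lif stood at -0.94, -1.003 and -0.18.

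Across the 21 gene lists, 8 stood outside the middle 95% of random lists in neutrophil-like cells (6 higher, 2 lower). In monocyte-like cells 16 did (9 and 7) and in macrophage-like cells 15 did (11 and 4). Random lists give about 1 in 20, but their genes are drawn independently. Genes of 1 programme can move together between any 2 libraries, so that rate is no measure of chance for these lists. The granule and bone marrow stage list was higher in monocyte-like (0.32) and macrophage-like cells (0.31) as well. The recruited monocyte programme had medians of 0.30, 0.22 and 0.09 in neutrophil-like, monocyte-like and macrophage-like cells. Its members were split, since of 25 in each class 6, 5 and 6 were at least 1.5-fold higher and 4, 4 and 4 lower. Ly6i and Plac8, among its members, were at least 2-fold lower in all 3 classes. Ly6c2, another member, stood at -0.88 in monocyte-like cells. Wound repair and lipid-associated macrophage genes had medians of 0.24, 0.16 and 0.05, and hypoxia and glycolysis genes of 0.08, 0.21 and 0.11. Iron handling and oxidative stress gave 0.09, 0.12 and 0.07, and B-1 cell and B cell activation genes gave 0.13, 0.14 and 0.15. Tissue-activated neutrophil genes had medians of 0.18 in both monocyte-like and macrophage-like cells and of -0.04 in neutrophil-like cells, where inflammatory genes stood at -0.01. Cell division genes had a median of -0.41 in monocyte-like cells, with 13 of 30 members at least 1.5-fold lower. The median was -0.11, -0.70 and 0.0447 within the 3 clusters of the class, and 0.0972 with monocyte-like and macrophage-like cells as 1 class. The list's UMIs were a similar part of the class total, at 20669 of 12971575 and 23512 of 15566568. Top2a was found in 32 of 983 and 27 of 1146 monocyte-like cells, and Mki67 in 42 and 76. The resident macrophage programme was at -0.36 in neutrophil-like cells and 0.03 in monocyte-like cells. In monocyte-like cells small negative medians were found for MHC class II genes (-0.13), efferocytosis and complement receptors (-0.11), inflammasome and pyroptosis genes (-0.12), immediate-early and heat-shock genes (-0.14) and follicular and marginal zone B cell genes (-0.17), and a small positive median for cytotoxic and effector lymphocyte genes (0.18), of which 0 of 11 were at least 1.5-fold higher and 3 were lower. Of these, the MHC class II, cytotoxic and inflammasome medians were not kept in 9, 12 and 12 of 17 alternatives, with ranges of -0.39 to 0.15, -0.45 to 0.20 and -0.19 to -0.00323. Wound repair genes were not kept in 5 of 17 alternatives in monocyte-like and in 7 of 17 in macrophage-like cells, nor were the resident programme in 9 of 16 and B-1 cell genes in 6 of 16 in neutrophil-like cells. In macrophage-like cells oxidative phosphorylation genes stood at -0.09, inflammasome genes at -0.12 and T cell quiescence and lymphoid homing genes at 0.17, which were not kept in 3, 8 and 7 of 17 alternatives, and iron handling and hypoxia genes were not kept in 5 and 4. Leukocyte adhesion and chemotactic receptors (0.07, 0.01 and 0.07) and apoptosis and survival genes, with medians of -0.09 and -0.04 in neutrophil-like and monocyte-like cells, lay within random lists in every one of the 3 classes. Genes at least 2-fold lower in all 3 classes numbered 8 (Aldh1l1, Gm13822, Ifi206, Ifi213, Irf7, Ly6i, Plac8 and Usp18). Those higher in all 3 numbered 7 (Ccl24, Csta2, Cstdc4, Lcn2, Retnlg, Saa3 and Wfdc21). Retnlg stood at only 1.46 and 5.97 CPM in monocyte-like cells, against 886 and 2647 CPM in neutrophil-like cells. A gene shared at such trace levels need not be made in all 3 classes, which was not tested. Several lists share genes, so their counts are not independent.

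**Figure D3:**
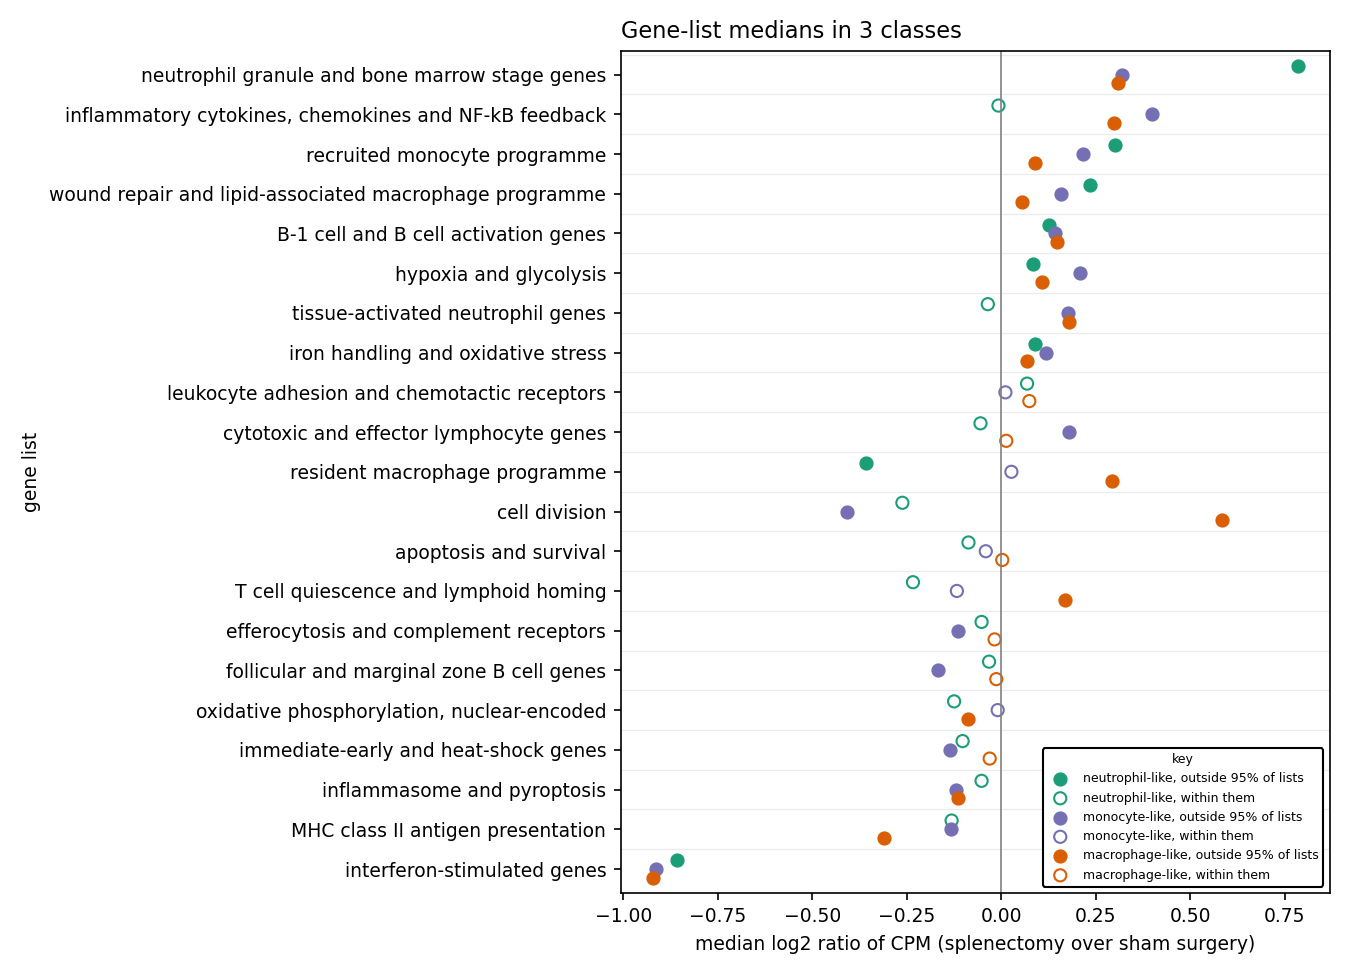
Median log2 ratio of CPM, splenectomy over sham surgery, of 21 gene lists in neutrophil-like, monocyte-like and macrophage-like cells. Filled points lie outside the middle 95% of 10000 random lists matched on expression; interferon-stimulated genes stand lowest at -0.86, -0.91 and -0.92.

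The smaller classes gave fewer counts. In conventional dendritic cell-like cells Saa3 stood at 4.30 CPM in the sham library and 41.3 CPM in the splenectomy library, Cd209d and Slpi had log2 ratios of 1.86 and 1.64, and Aldh1l1, Ly6a and Hdc of -2.95, -1.66 and -1.60. Among the genes that met the naming limits, B cell-like cells differed most in Ifitm2, Hist1h2ae and S100a4 (2.93, 2.59 and 2.56) and in Irf1, Gadd45b and Irs2 (-1.79, -1.12 and -1.05). The first 3 rest on few cells, since S100a4 was found in 17.3% and 12.5% of the class, Hist1h2ae in 10% and 13.4% and Ifitm2 in 9.09% and 18.8%. The complement receptor Cr2 and the low-affinity IgE receptor Fcer2a, markers of marginal zone and follicular B cells of the spleen, were found in 5.05% and 24.2% of thinned sham B cell-like cells and in 1.98% and 23.8% of those of the splenectomy library, with overlapping intervals. In T cell-like cells Ikzf2, Ccl5 and Cd8b1, a transcription factor of T cell subsets, a chemokine and a chain of CD8, had log2 ratios of 2.65, 1.58 and 1.05. Chil3, H2-Ab1 and Cd74 were the lowest named genes of that class, at -4.47, -3.54 and -3.17, and all 3 genes were highest in other classes, Chil3 in monocyte-like cells and the others in conventional dendritic cell-like cells. The shares of T cell-like cells with them were close (10.1% and 10.8%, 11.6% and 12.2%, and 20.3% and 17.6%), so that few cells carry these ratios. Nonclassical monocyte-like cells differed in Sdc4, Hpgd and Fn1 (2.76, 2.17 and 1.63) and in the neutrophil genes Mmp9, S100a9 and G0s2 (-3.47, -2.65 and -2.40). Endothelial cell-like cells differed in Mgp, Rgs5 and Tnnt2 (1.81, 1.75 and 1.69), markers of fibroblasts, mural cells and cardiomyocytes, and in Ccl12, Ccl7 and Wfdc17 (-4.27, -3.85 and -3.71), of which Ccl12 and Ccl7 were highest in macrophage-like and Wfdc17 in neutrophil-like cells. Wfdc17 was found in 12.2% and 16.5% of the endothelial cell-like class, and S100a9 in 68.4% and 66.7% of nonclassical monocyte-like cells, so that few cells carry those ratios too. Gzmb, a cytotoxic granule protease, was found in 70.1% and 72.4% of thinned natural killer cell-like cells. Genes at least 2-fold higher and lower numbered 27 and 63 of 5751 in conventional dendritic cell-like cells, 29 and 3 of 1311 in B cell-like cells, 4 and 38 of 960 in T cell-like cells, 11 and 43 of 2288 in nonclassical monocyte-like cells and 17 and 43 of 1619 in endothelial cell-like cells. The T cell-like and endothelial cell-like classes rest on 69 and 74, and on 90 and 85 cells.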

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

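The tests of library scaling, of interferon-stimulated genes most abundant in neutrophil-like cells, of neutrophil-like cells matched on UMIs and of neutrophil markers in monocyte-like cells were chosen after results were seen, and the other tests below were set before.

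Interferon-stimulated genes were lower in the splenectomy library in all 3 large classes, which may reflect the missing spleen, library scaling, free RNA or another mix of clusters. Scaling was excluded, since the median of 5343 neutrophil genes was -0.0551. Another mix of these clusters could be part of the cause but not all of it, since the list's median stayed at -0.45 (-0.57 to -0.33) or lower in each of 12 clusters. The clusters were formed without interferon-stimulated genes. Another share of cells that express them within a cluster was therefore not tested and stays open. Free RNA from other cells was first judged excluded because the loss was 2.30 times what foreign RNA could bring, but that bound was wrong to rely on because it assumed the makeup of the free RNA, so it leaves the question open. For 10 members more abundant in sham neutrophil-like cells than in each of 15 other clusters the median was -0.66 (-0.87 to -0.54). This argues against free RNA from those 15 clusters, for these members only. Clusters with fewer than 50 sham cells and removed cells were not compared. The members were chosen by their sham level, which also enters their ratio. The splenectomy itself cannot be told from any other difference between 2 single libraries and stays open.

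Granule and bone marrow stage genes were higher in neutrophil-like cells of the splenectomy library, which might reflect younger neutrophils in the heart, deeper sampling of each cell or more residual blood. With cells grouped into 4 bins by UMIs the lowest median was 0.44, with an interval of 0.00 to 1.28 over members. In another bin the median was 0.48 and its interval reached below 0 (-0.17 to 1.01). In 1514 cells per library matched on UMIs the median was 0.72 (0.08 to 1.05), against 0.78 in all cells and 0.88 in cells thinned to 2000 UMIs. Depth is thus unlikely to be the whole cause, but the intervals over members reach too low to exclude it. Haemoglobin and platelet genes had a median of 0.21 over 14 genes. Hba-a2, Hbb-bs and Hbb-bt stood at 1.18 (0.52 to 1.87), 1.34 (0.90 to 1.80) and 1.13 (0.08 to 2.27), but Hba-a1, the haemoglobin gene with most counts, at 0.16 (-0.18 to 0.51). Ppbp stood at 0.69 (0.62 to 0.77), but was also a leading gene of the macrophage-like cluster marked by Ccl24, Serpinb2 and Il6. Itga2b, Treml1 and Nrgn, the only negative ones, stood at -0.25 (-1.16 to 0.65), -0.41 (-1.66 to 0.79) and -0.06 (-0.32 to 0.20). Most of the genes were thus higher, the intervals of the negative ones and of several positive ones spanned 0, and more residual blood remains possible. Whether the neutrophils were younger was not tested, and the limits for depth here and for the mix of clusters above were tightened after their values had been seen.

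S100a8, Wfdc21 and Lcn2 were higher in monocyte-like cells of the splenectomy library, which could come from neutrophil RNA in the same droplets or from expression in monocytes. The smallest ratio of observed CPM to the CPM that neutrophil RNA allows, judged by S100a9, was 5.24 in the splenectomy library. RNA of the kept neutrophil-like clusters thus does not account for the level of these 3 genes there. It allows 396, 12.5 and 14.0 CPM, against 2075, 178 and 321 observed. Sham ratios were also over 1, at 2.71, 12.1 and 27.0, so the ratio measures the level of these genes and not their rise. The median monocyte-like cell held 0 UMIs of Wfdc21 and of Lcn2 in both libraries. This test replaced 2 earlier ones, in which S100a8 had a log2 ratio of -0.38 (-0.58 to -0.18) in B cell-like, T cell-like and endothelial cell-like cells pooled (1.59, -1.66 and -1.79 in each class, so that the pool mixed opposite directions), and 10 other neutrophil markers had a median of 0.36 in monocyte-like cells with 1 above 1. Expression in monocytes stays open, since RNA from cells that were not captured was not tested.

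Cell division genes differed by 0.99 between macrophage-like and monocyte-like cells in their median log2 ratio, a difference that was not tested. The resident macrophage programme differed by 0.65 between macrophage-like and neutrophil-like cells, which was not tested either. Endothelial cell-like cells held 1.54% and 1.77% of the libraries although cells had been selected for CD45, and fibroblast-like cells held 0.308% and 0.437%. An unnamed cluster led by Gm26917, Rmrp and Lars2 with a median of 1577 UMIs held 5.88% and 6.60%. Another unnamed cluster, led by Slc26a11 and Gstm1, held 0.291% and 0.312%, and a cluster led by the cardiomyocyte genes Myl2, Myl3 and Tnni3 held 0.343% and 0.187%. A cluster led by Saa3, Prg4 and Alox15 held 15 cells, 0.312%, in the splenectomy library and 3 cells in the sham library.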

How the results depend on the processing

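No paired analysis was possible because each group holds 1 library and the labels give no replicate numbers. The splenectomy cannot be separated from the library, the animals behind each library are not counted in the sources used here, and no interval covers differences between animals. Of the 23 alternatives 17 were set before the data were examined and 6 were chosen after seeing the data. Of class share differences 111 were the same, 19 moved and 5 reversed; of list medians 545 were the same, 81 were weaker and 29 reversed; and of named-gene ratios 639 were the same, 407 moved and 18 reversed. Interferon medians stayed between -0.88 and -0.49 in neutrophil-like, -1.003 and -0.69 in monocyte-like and -1.07 and -0.71 in macrophage-like cells. Fibroblast-like, conventional dendritic cell-like or plasmacytoid dendritic cell-like cells were not found in some alternatives. Class shares moved in part because clusters lost their name. With such cells counted in the class they hold in the report, the neutrophil-like difference was -6.02 to -5.25 and that of monocyte-like and macrophage-like cells as 1 class 4.20 to 5.61 in 11 reclusterings, but this count takes its classes from the report and is no independent check. For the other results below that were not kept, the cause was not tested. Share differences are in percentage points, and medians and ratios are log2.

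With at least 500 genes per cell the macrophage-like share difference was -3.57, cytotoxic genes in monocyte-like cells had a median of -0.45 and MHC class II genes in macrophage-like cells of 0.00278. With at most 10% mitochondrial UMIs the monocyte-like and macrophage-like differences were 9.80 and -4.36, cytotoxic genes in monocyte-like cells had -0.0203, and macrophage-like cells had 31 genes at least 2-fold higher and 2 lists apart on the low side. Without doublet removal the monocyte-like and macrophage-like differences were 1.78 and -3.82, 1 list was apart on the low side in neutrophil-like cells, and monocyte-like cells had 38 higher genes, medians of 0.11 for MHC class II and -0.21 for cytotoxic genes, and ratios of -0.40 for Arg1 and -0.20 for Spp1.

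At Leiden resolution 0.5 the monocyte-like and macrophage-like differences were 2.36 and 3.11. Monocyte-like cells had 38 higher genes, medians of 0.10 for MHC class II and -0.19 for cytotoxic genes, and ratios of -0.36 for Arg1 and -0.50 for Spp1, and macrophage-like cells had 100 higher genes. At resolution 2.0 the neutrophil-like and monocyte-like differences were -1.30 and 1.59. Medians in monocyte-like cells were 0.15 for MHC class II, -0.0692 for wound repair and -0.23 for cytotoxic genes, with Arg1 at -0.53 and Spp1 at -0.96, and macrophage-like cells had -0.0368 for recruited monocyte genes, -0.0426 for wound repair and -0.00351 for Arg1.

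With the libraries clustered apart the monocyte-like and macrophage-like differences were 10.8 and -15.6. Higher genes numbered 101 in monocyte-like and 16 in macrophage-like cells, 128 genes were lower in macrophage-like cells, and 5 lists were apart high and 7 low there. Medians in macrophage-like cells were -0.0188 for inflammatory genes, -0.0176 for tissue-activated neutrophil genes, -0.00400 for cell division, -0.00581 for T cell quiescence and -0.0646 for B-1 cell genes, and ratios were -0.94 for Il6, -1.003 for Serpinb2 and -0.18 for Lif. With cells thinned to 2000 UMIs the neutrophil-like difference was -2.44. Higher and lower genes numbered 32 and 46 in neutrophil-like, 32 and 54 in monocyte-like and 12 and 30 in macrophage-like cells, and lists apart were 1 low in neutrophil-like, 4 low in monocyte-like and 7 high in macrophage-like cells. In macrophage-like cells hypoxia had a median of -0.0249, inflammasome genes of 0.0232 and Timd4 a ratio of -0.10.

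The following 5 settings are among those chosen after seeing the data. With the genes of the state lists kept in the clustering, neutrophil-like, monocyte-like and macrophage-like differences were -0.34, 2.09 and 0.42, 1 list was apart low in neutrophil-like cells, and macrophage-like cells had 38 higher genes. Monocyte-like cells then had 0.14 for MHC class II, -0.16 for cytotoxic genes, -0.54 for Arg1 and -0.83 for Spp1. With these genes kept at resolution 0.5 the differences were -2.77, 1.24 and 0.32, 1 list was apart low in neutrophil-like cells, and macrophage-like cells had 31 higher genes and Ly6a at 0.46. Monocyte-like cells had 0.15 for MHC class II, -0.12 for cytotoxic genes, -0.60 for Arg1 and -0.81 for Spp1. With the non-marker genes of every list left out of the clustering the neutrophil-like difference was 5.95, with 1255 of 2254 and 465 of 1573 of these cells left without a name, 30 genes were lower and 1 list apart low in that class, the resident macrophage programme had 0.11 there, and cytotoxic genes had -0.38 in monocyte-like cells. With Scrublet's own threshold the monocyte-like and macrophage-like differences were 2.89 and -5.41, 1 list was apart low in neutrophil-like cells and 29 genes were lower in macrophage-like cells. Monocyte-like cells had 0.0763 for MHC class II, -0.17 for cytotoxic genes, -0.0938 for Arg1 and -0.0551 for Spp1. With monocyte-like and macrophage-like cells as 1 class the difference was 5.19, 4 lists were apart low, cell division had 0.10 and cytotoxic genes -0.11.

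With at least 200 counts, higher and lower genes numbered 27 and 28 in neutrophil-like, 27 and 57 in monocyte-like and 22 and 29 in macrophage-like cells. With at least 20 counts they numbered 120 and 202, 131 and 178, and 149 and 101, and at 1.5-fold 196 and 422, 243 and 366, and 216 and 224. With random lists not matched, 3 lists were apart low in monocyte-like cells. Unthinned, the difference in Ly6c2 share was -10.9 points, and at 2 UMIs those of Ccr2 and Il1b were -3.20 and -1.07 points.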

Other observations

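Aldh1l1, an enzyme of folate metabolism not on any of the lists, was among the lowest genes of 3 classes. Its CPM was 22.0 in the sham library and 4.18 in the splenectomy library in monocyte-like cells, 14.0 and 3.19 in macrophage-like cells and 22.2 and 2.88 in conventional dendritic cell-like cells. The gene lies on chromosome 6 from 90486427 to 90600203 in mm10 (ENSMUSG00000030088), and its highest level of all classes was in nonclassical monocyte-like cells. Ly6a, an antigen that interferons induce, was low beside it in the same 3 classes, with log2 ratios of -1.94, -1.32 and -1.66.

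In B cell-like cells cell division genes had a median log2 ratio of 0.96, with 14 of 18 members at least 1.5-fold higher in the splenectomy library, but few cells carried them. The 5 cells with most held 67.8% of the list's UMIs in the splenectomy library and 11.6% in the sham library. Top2a, a topoisomerase of dividing cells, was found in 3 of 110 and 12 of 112 cells, and Pclaf, a clamp-associated factor, in 1 and 2 cells. Conventional dendritic cell-like cells showed the opposite, with a median of -0.57 and 16 of 33 members lower. In that class, of 306 and 217 cells, Top2a was found in 39 and 15 cells and Pclaf in 31 and 13. The shares of cells with Mki67, at 48 and 29 cells, were closer. The 5 cells with most held 22.6% and 20.3% of the list's UMIs.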
